A study of Mus musculus with 8 samples.

How the data were processed

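Total RNA from mouse brain was sequenced for 8 libraries, 4 labelled control and 4 labelled Akap11 conditional knockout (cKO), and each library's group and replicate number were taken from its title. The tissue label reads as brain with no region. The design text speaks of mice and of replicates, without saying that each library is a separate mouse, so p-values measure the spread between these libraries. Brain region, age, sex, litter, recombinase line, the targeted exons and sequencing batch are not given in the sources used here.

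The deposited values are whole-number read counts per gene, 1 file per library, with no normalization. Per the submitters' processing notes, HISAT2 and the GRCm39 mouse build were used; their versions, the counting program, its strand setting and its annotation are not given in the sources used here. Per the labels' protocols, RNA was extracted with a column kit and the libraries were made and sequenced by a commercial provider. Each file lists 57186 genes by Ensembl identifier, of which 51880 were matched to a symbol; genes without a symbol held 0.514% of the reads in genes. Each file also ends with 5 entries that name no gene: reads in no feature, ambiguous reads, reads of low mapping quality, unaligned reads and reads with several alignments. These stayed out of library sizes and tests. As shares of all listed reads they ranged over the libraries from 4.35% to 6.04% for no feature, 5.14% to 10.1% for ambiguous, 2.15% to 7.18% for low quality, 3.31% to 10.4% for unaligned, and 4.10% to 4.39% for several alignments. Because the strand setting is not given, reads of overlapping genes on opposite strands cannot be told apart by these counts.

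Genes were filtered with filterByExpr, which kept 16766 of the 32202 genes with at least 1 read, and libraries were scaled by TMM. The cKO and control groups were compared with the quasi-likelihood test of edgeR 4.0.16 (robust fit, group as the only term) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Levels are TMM-normalised CPM (read counts scaled to a common library size), computed here from the deposited counts, given as mean ± SD over 4 libraries. A log2 fold change is cKO minus control, with its standard error (SE) and, where given, its 95% interval. Principal components used log2 CPM with a prior count of 2.

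The rule for the genes named was fixed before the data were examined, as were the main test, the gene lists and the alternatives, except those named below as added later. It took Akap11 first. Then came genes past the threshold whose 4 cKO libraries all lay above or all below the 4 control libraries, with a mean CPM of at least 1, up to 12 per direction, leaving out predicted genes, pseudogenes and sex-specific transcripts. As few qualified, the genes with the lowest p-values not past the threshold were added up to 10 in all, Akap11 included. Up to 4 members with the lowest p-values were named per list, some of which are not reported here, and the PKA subunit genes, Gsk3a and Gsk3b were always given. Ddx3y and Xist were named to read the sex of the libraries. Wbp4 was named as the neighbour of Akap11 with the lowest p-value, and AC133525.2 for its overlap with Aqp4. Any other gene named was chosen after its values were seen, and this is said beside it.

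Of 47 gene lists written from general knowledge (pathways, cell types, brain regions, cell states and technical sets), 46 had at least 5 tested members and were tested with camera in limma 3.58.1 on voom values, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera asks whether the test statistics of a list's genes differ on average from those of all other genes. The alternatives were an estimated correlation and fry, which tests whether a list's genes move on balance 1 way. Members were also counted by the edgeR test over all genes and adjusted over the list alone. A list's mean log2 CPM per library, relative to the control mean, was compared by a two-sided exact permutation test over the 70 assignments of libraries to groups.

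The alternatives were DESeq2 1.42.0 with its own filter, its size factors in the edgeR fit, library totals alone, 2 other low-count filters, limma voom with and without sample weights, removal of mitochondrially encoded genes, the replicate number as a block, 1 surrogate variable from sva 3.50.0, and each library left out in turn. A sex covariate was planned only if both sexes occurred in both groups, and was not run. Of the alternatives added after seeing the data, 1 leaves out control replicate 1 and cKO replicate 1 together, and 1 fits GC-content offsets per library by loess with a span of 0.5. For the mitochondrially encoded list, an estimated correlation was also added in the 3 fits in which its call with the preset correlation turned. The same was added for all lists in the fit with GC-content offsets and in each fit that leaves out libraries, has the block or has the surrogate variable. GC content came from the longest transcript of each gene in the GENCODE M21 annotation of GRCm38, which covered 98.2% of the tested genes. That annotation is of an older build than the counts, so it was used for GC content, gene type, chromosome names and gene order, and no coordinates are given.

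The reads in genes per library ranged from 13841218 to 19991942. The common dispersion corresponded to a biological coefficient of variation of 8.37%. No 2 replicates were identical, and each pair within a group differed by more than sampling noise, with a chi-square per degree of freedom from 2.99 to 15.1 over genes with at least 20 reads in the pair. The edgeR step was tested on simulated data: 5 simulations of this comparison over 16766 genes, with 200 genes changed by known folds, 50 per fold. The share recovered in the right direction was 37.6% of genes changed by the smallest fold, a log2 change of 0.32, 69.6% of genes changed 1.5-fold, 92.8% of those changed 2-fold and 98.0% of those changed 3-fold. On average 7.16% of the calls were false, above the nominal 5%. Recovery would be lower where fewer genes change. The changed genes were drawn from those with a mean CPM of at least 1. Genes were simulated independently, with no library set apart and no GC-content or length trend.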

Results

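Brain RNA of mice with a conditional knockout of Akap11 was compared with brain RNA of control mice, with 4 libraries per group. Akap11 encodes an A-kinase anchoring protein, which tethers protein kinase A (PKA). The series title describes the gene as a risk gene for bipolar disorder and schizophrenia, as a receptor for autophagy and as a regulator of the PKA network and of synaptic transmission. The comparison asks which brain transcripts differ when the gene is deleted. Protein levels, PKA activity and autophagic degradation are not measured by these counts. Reads in genes numbered 16706350, 15752877, 18751113 and 19818313 in control replicates 1 to 4, and 13841218, 19991942, 19667928 and 18291177 in cKO replicates 1 to 4. All 8 libraries held reads of the Y-linked gene Ddx3y (803 to 1615) and at most 3 reads of Xist, the transcript of the inactive X chromosome, so all read as male. In cKO replicate 1, 63.8% of all listed reads lay in genes, against 73.7% to 79.7% in the other libraries. This library had the highest shares of ambiguous (10.1%), low mapping quality (7.18%) and unaligned reads (10.4%). The next highest shares in any library were 6.16%, 4.04% and 6.66%. On the first principal component (23.3% of the variance) cKO replicate 1 lay at 39.1, with the others between -10.5 and 0.48. Control replicate 1 lay apart on the second component (18.1%), at 31.0.

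Akap11 itself was lower in every cKO library than in every control library. Its level was 323 ± 35.3 CPM (SD, n = 4) in control and 228 ± 12.7 CPM (SD, n = 4) in cKO brain. The gene (ENSMUSG00000022016, chromosome 14) fell by 29.3%, a log2 fold change of -0.50 (SE 0.069, 95% interval -0.64 to -0.35) with an edgeR adjusted p of 0.0103. Single control libraries held 373, 312, 315 and 291 CPM, and single cKO libraries 220, 214, 237 and 240 CPM. An exact permutation test on the CPM values gave a two-sided p of 0.0286, the smallest possible for 4 against 4. The counts cover the whole gene, so reads from exons outside the deleted part and from cells without the recombinase are included. The call ended without control replicate 2 (-0.52, edgeR adjusted p 0.0616), without cKO replicate 2 (-0.47, edgeR adjusted p 0.104) and with 1 surrogate variable (-0.47, edgeR adjusted p 0.0676).

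**Figure D1:**
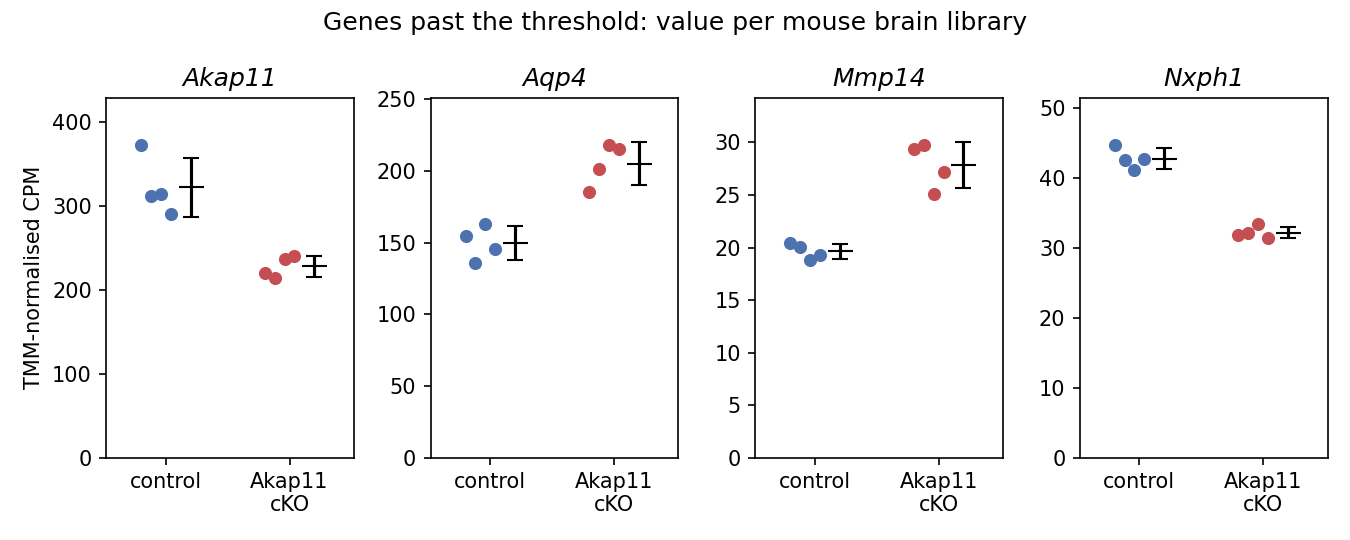
TMM-normalised CPM (vertical axes, starting at 0) of Akap11, Aqp4, Mmp14 and Nxph1 in the 4 control and 4 Akap11 cKO libraries; each point is a library and the bars give the mean and SD. In each panel the groups do not overlap, with Akap11 cKO libraries between 214 and 240 CPM and control libraries between 291 and 373 CPM.

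Beyond Akap11, 3 of the 16766 genes tested changed: Aqp4 and Mmp14 rose and Nxph1 fell. Aqp4 (ENSMUSG00000024411, chromosome 18), the water channel of astrocyte endfeet, rose 1.37-fold, from 149 ± 11.8 to 205 ± 14.9 CPM (SD, n = 4 per group). Mmp14 (ENSMUSG00000000957, chromosome 14), a membrane-anchored matrix metalloproteinase, rose 1.42-fold, from 19.6 ± 0.709 to 27.9 ± 2.17 CPM. Nxph1 (ENSMUSG00000046178, chromosome 6), a secreted ligand of alpha-neurexins at synapses, fell by 24.7%, from 42.8 ± 1.51 to 32.2 ± 0.847 CPM. The log2 fold changes were 0.46 for Aqp4 (SE 0.067, edgeR adjusted p 0.0104), 0.50 for Mmp14 (SE 0.083, edgeR adjusted p 0.0333) and -0.41 for Nxph1 (SE 0.068, edgeR adjusted p 0.0333). In all 3 genes the 4 cKO libraries lay on 1 side of the 4 control libraries. In total 4 genes passed the test, 2 higher and 2 lower.

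These 3 calls were lost in most fits with 1 library fewer, while the folds stayed within the ranges given here. Over the 8 fits that leave out 1 library, Aqp4 ranged from 0.41 to 0.50 and passed in 3 fits (without control replicate 1, control replicate 3 or cKO replicate 1), with edgeR adjusted p from 0.000965 to 0.159. Mmp14 ranged from 0.47 to 0.55 and passed in 1 fit (without cKO replicate 3), and Nxph1 ranged from -0.43 to -0.38 and passed in 1 fit (without cKO replicate 1), with edgeR adjusted p up to 0.218 and 0.238. DESeq2 called the same 4 genes and limma voom called Akap11 and Aqp4. With 1 surrogate variable the calls of Mmp14 and Nxph1 ended (edgeR adjusted p 0.0782 and 0.0676), as they did with both libraries that stand apart left out (0.0591 and 0.0952), and Nxph1 also missed the threshold with library totals (0.0508). Aqp4 overlaps an antisense gene, AC133525.2, which held 158 reads over the 8 libraries.

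No further gene passed with the low-count filter used. The next by p-value was Igsf1, an X-linked immunoglobulin superfamily gene, at 17.1 ± 2.82 CPM in control and 25.2 ± 3.50 CPM in cKO brain, with a log2 fold change of 0.55 (SE 0.12, edgeR adjusted p 0.464). With no low-count filter edgeR also called Igsf1 (adjusted p 0.000179; 0.000179 to 0.999 over its alternatives), Gfap and Gm21887, the last named after its values were seen. The following 5 each had an edgeR adjusted p of 0.889. Tst, a mitochondrial sulfurtransferase, had a log2 fold change of 0.37 (SE 0.095), Zbtb2 0.40 (SE 0.10) and Radil 0.38 (SE 0.098). Trps1, a zinc finger transcriptional repressor, had -0.32 (SE 0.080) and Lars2, the mitochondrial leucyl-tRNA synthetase, -0.24 (SE 0.062).

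An unadjusted p under 0.05 was reached by 802 genes, 4.78% of those tested, where 5% would be reached by chance; 481 of them were higher and 321 lower. The higher genes made up 60.0% of these, 49.4% with GC-content offsets and 49.7% without cKO replicate 1. Across 10331 genes with a mean CPM of at least 10, the log2 fold changes correlated with GC content (Spearman's rho 0.494). The correlation was 0.192 without cKO replicate 1 and 0.0958 with GC-content offsets. A correlation with the length of the longest transcript was also seen (rho -0.269). It remained at -0.251 without cKO replicate 1 and at -0.185 with GC-content offsets. Among single libraries, control replicate 1 correlated most strongly with length (rho 0.326), and cKO replicate 2 nearly as strongly in the other direction (rho -0.308). Genes are not independent replicates in these correlations, and a length trend was not corrected for in any fit. The 2 groups of 4 libraries did not overlap for 263 genes that were higher and 233 that were lower, together 2.96% of the genes, where chance gives 2.86%. The 95% interval excluded changes above 1.5-fold in either direction for 12871 genes (76.8%) and above 2-fold for 15485 genes (92.4%). Log2 changes above 0.32 in either direction were excluded for 8963 genes (53.5%). These bounds hold for RNA of the whole sample, in which Akap11 itself fell by 29.3%. Cells without the recombinase are included, so larger changes confined to some cells are not excluded.

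At the RNA level, none of the 9 tested genes for PKA subunits and PKA inhibitors passed the adjusted edgeR test. The catalytic subunit genes stood at 185 ± 2.42 and 184 ± 1.67 CPM for Prkaca, and 644 ± 22.1 and 627 ± 18.8 CPM for Prkacb, in control and cKO brain (SD, n = 4). The 95% intervals of their log2 fold changes ran from -0.12 to 0.10 for Prkaca and from -0.15 to 0.07 for Prkacb. Prkar1a, encoding a type I regulatory subunit, was at 865 ± 9.86 CPM in control and 776 ± 47.3 CPM in cKO brain. All 4 cKO libraries lay below the controls, but the log2 fold change of -0.16 (SE 0.055, 95% interval -0.27 to -0.04) did not pass by edgeR, with an adjusted p of 0.889, or 0.0973 adjusted over the list alone. Its unadjusted edgeR p was 0.0108. The log2 fold change was -0.12 without cKO replicate 1.

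The other regulatory subunit genes had log2 fold changes of 0.04 for Prkar1b (SE 0.062), -0.01 for Prkar2a (SE 0.061) and -0.07 for Prkar2b (SE 0.071). Without cKO replicate 1 these were -0.03, -0.0093 and -0.02, so that the sign of Prkar1b turned, as it did with GC-content offsets (-0.02). The inhibitor genes Pkig, Pkia and Pkib had 0.13, -0.07 and -0.14, or 0.12, -0.03 and -0.10 without that library. As a list, PKA subunits and inhibitors did not pass camera (median -0.04, adjusted p 0.205). The list of A-kinase anchoring proteins other than Akap11 did not pass either (20 tested, median -0.05, camera adjusted p 0.176). Its 4 members with the lowest p-values were Akap8l at 0.21, Map2 at -0.19, Akap6 at -0.17 and Akap9 at -0.19, none past edgeR's threshold over all genes or adjusted over the list alone. By edgeR, 6 of the 20 anchoring protein genes reached an unadjusted p under 0.05, 5 lower and 1 higher. The count was 0 without control replicate 1, 1 without cKO replicate 1, 2 without cKO replicate 3 and from 5 to 7 in the other fits that leave out 1 library; with GC-content offsets it was 2. Among 25 adenylyl cyclases and cAMP phosphodiesterases, no gene passed (camera adjusted p 0.205), with Pde10a at -0.12 and Pde11a at -0.26.

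The kinase genes Gsk3a and Gsk3b, whose products bind AKAP11, had log2 fold changes of 0.03 (SE 0.061) and -0.10 (SE 0.073). Without cKO replicate 1, Gsk3a stood at 0.01 and Gsk3b at -0.03, and with GC-content offsets Gsk3a turned to -0.05 while Gsk3b stood at -0.09. The list of GSK3, protein phosphatase 1 and VAP partners had no member past the threshold among 13 (median -0.02, camera adjusted p 0.595). Among 17 Wnt and beta-catenin target genes none passed, and the list had a camera adjusted p of 0.899, with a median of -0.01 but a mean of 0.02. Rnf43, an inhibitor of Wnt receptors, stood at 0.45 (SE 0.19).

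**Figure D2:**
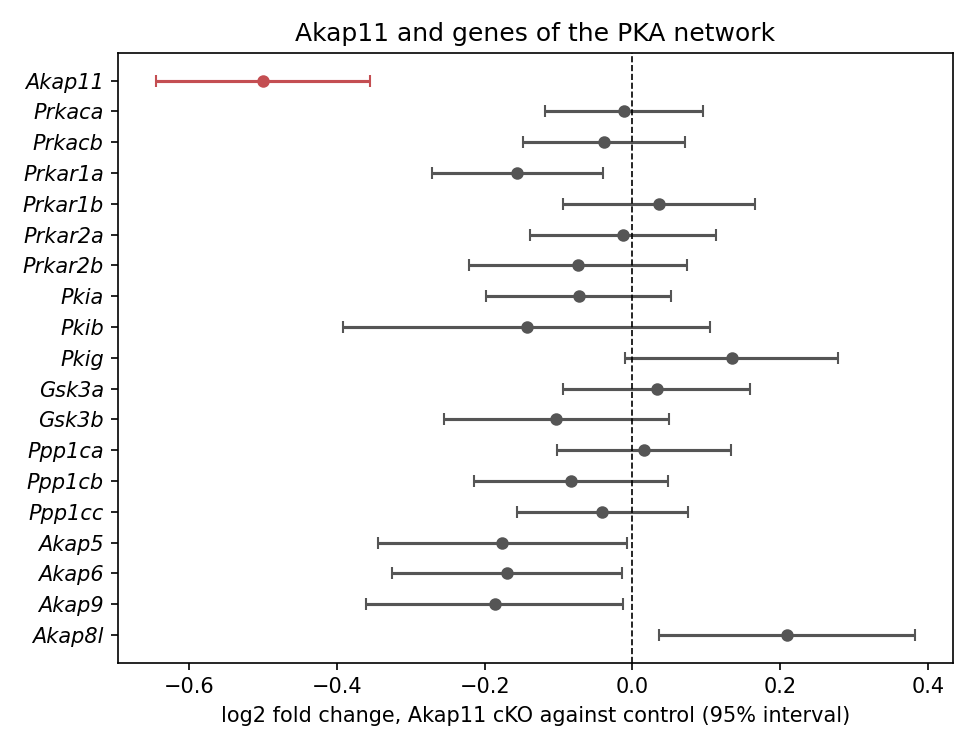
Log2 fold change (horizontal axis, Akap11 cKO against control) of Akap11 and of genes for PKA subunits, PKA inhibitors, GSK3, protein phosphatase 1 and other anchoring proteins; points are edgeR estimates and bars their 95% intervals. Akap11, in red, lies at -0.50, while Prkaca lies at -0.01 and Prkar1a at -0.16; of the genes drawn, Akap11 alone passed the adjusted test.

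Genes of autophagy and the lysosome, examined because the title names autophagy, gave no calls. These are RNA levels, which do not show whether autophagy itself or the turnover of proteins differed. Among 20 selective autophagy receptor genes the median log2 fold change was -0.03 (camera adjusted p 0.205), and the member with the lowest p-value was Optn, encoding optineurin, at -0.24 (SE 0.096). The 40 genes of the core autophagy machinery had a median of 0.01 (camera adjusted p 0.962), with Map1lc3a at 0.15 (SE 0.066) and Atg10 at -0.30 (SE 0.14). The 52 lysosomal genes also had a median of 0.01 (camera adjusted p 0.473), with Arsa, encoding arylsulfatase A, at 0.19 (SE 0.081). By edgeR, an unadjusted p under 0.05 was reached by 1 receptor gene, 2 core autophagy genes and 2 lysosomal genes. With 1 library left out, the receptor count ran from 0 (without control replicate 3) to 3 (without control replicate 4 or cKO replicate 4), and the core count from 0 (without control replicate 3) to 2. The lysosomal count ran from 0 (without cKO replicate 1) to 5 (without cKO replicate 4). With GC-content offsets the 3 counts were 1, 0 and 1. No member passed over all genes, adjusted over the list alone, or among the calls of DESeq2 and limma voom.

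Over all gene lists, 9 of 46 passed camera with the preset correlation of 0.01, 1 towards higher and 8 towards lower values in cKO brain. With an estimated correlation 0 of the 46 passed, with adjusted p from 0.795 to 0.837 for these 9, and fry called 0; in each, the proteasome list alone had an unadjusted p under 0.05. The exact permutation test of list means per library gave a p under 0.05 for 1 list before adjustment and for 0 after it. The smallest p this test can give is 0.0286, so after adjustment over 46 lists a list alone cannot pass. The 0 after adjustment therefore carries no weight. None of the 9 kept its call in all 8 fits that leave out 1 library. With GC-content offsets all 9 passed in the same direction and 5 more did, so that 14 passed, 2 towards higher and 12 towards lower values; with an estimated correlation in that fit 0 passed (adjusted p 0.786 for each of the 14).

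Some lists outside the 9 passed camera with the preset correlation once libraries were left out. Without control replicate 3 there were 9 of them: presynaptic release, excitatory postsynaptic, GABA receptor, cytosolic ribosomal, astrocyte, oligodendrocyte, cortical, hypothalamic, and midbrain and hindbrain genes. Without cKO replicate 1 there were 5: cyclases and phosphodiesterases, presynaptic release, GABA receptors, mitochondrially encoded transcripts and oligodendrocyte precursors. Without cKO replicate 2 there were 5: excitatory postsynaptic, neuropeptide, cytosolic ribosomal, interferon-stimulated and striatal genes. Without control replicate 4 there were 3 (anchoring proteins, presynaptic release and GABA receptors), without control replicate 1 there were 2 (cytosolic ribosomal proteins and astrocytes), and without cKO replicate 4 there were 2 (oligodendrocytes, and midbrain and hindbrain). Leaving out both libraries that stand apart gave 2 (mitochondrially encoded transcripts and astrocytes), and 1 surrogate variable gave 4 (those gained without cKO replicate 1 other than GABA receptors). In each of these fits 0 lists passed with an estimated correlation, with adjusted p of at least 0.553. The members named from these lists are given with their values, and apart from Aqp4 and Nxph1 no list member passed edgeR's test over all genes.

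**Figure D3:**
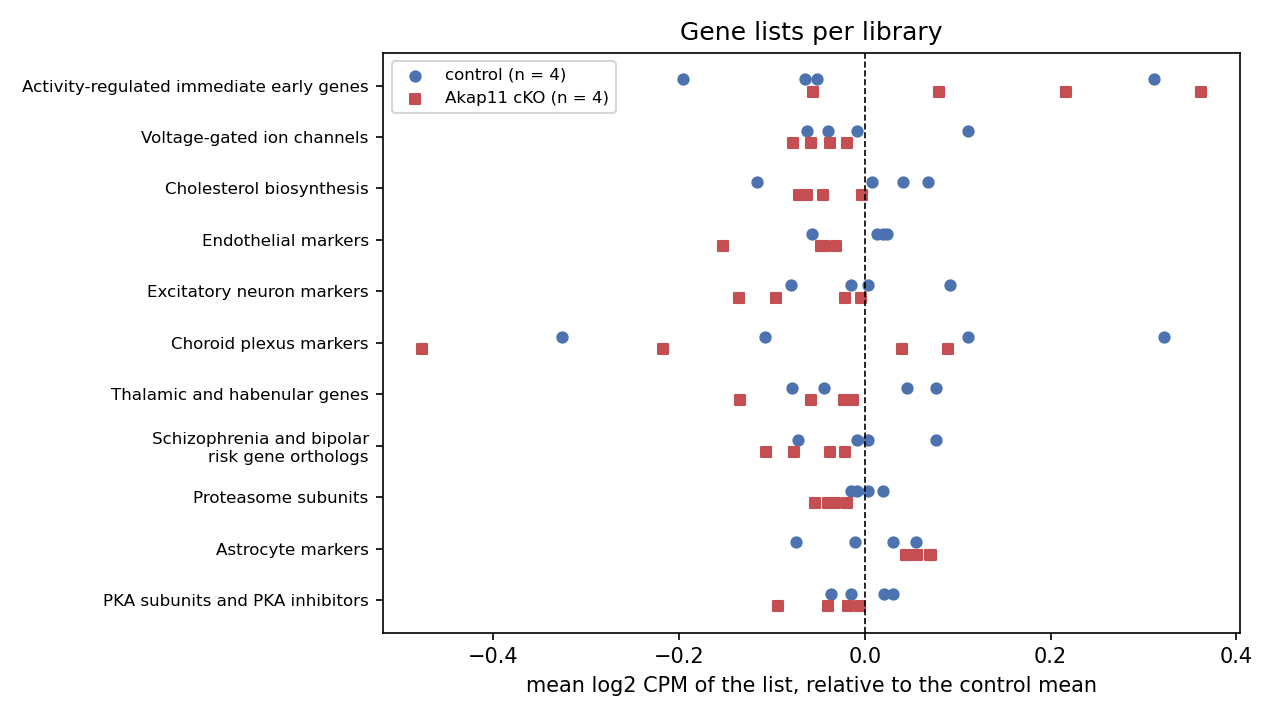
Mean log2 CPM of the members of 11 gene lists per library, relative to the control mean (horizontal axis); circles are the 4 control and squares the 4 Akap11 cKO libraries. The upper 9 lists passed camera with the preset correlation and the lower 2 did not; in the proteasome list the groups do not overlap, with an exact permutation p of 0.0286.

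Immediate early genes, which neurons transcribe within minutes of activity, were the list that passed towards higher values. Of 36 tested, 30 had a positive log2 fold change, with a median of 0.12 (camera adjusted p 0.00114). An estimated correlation gave an adjusted p of 0.830. Dusp1, a phosphatase of MAP kinases, stood at 0.44 (SE 0.20), Ccn1 at 0.34 (SE 0.18), Sik1 at 0.23 (SE 0.14) and Rheb at -0.09 (SE 0.057), and by edgeR 0 members reached an unadjusted p of 0.05. The list mean was 0.15 ± 0.18 in cKO libraries against an SD of 0.22 among control libraries (exact permutation p 0.286, n = 4). The call was lost without control replicate 3 and without cKO replicate 2 (camera adjusted p up to 0.222).

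Voltage-gated ion channels lay towards lower values, with 31 of 41 members negative and a median log2 fold change of -0.05 (camera adjusted p 0.00825). The list did not pass with an estimated correlation (adjusted p 0.795). Members with the lowest p-values were the calcium channel gene Cacna1e (-0.20, SE 0.071), the potassium channel genes Kcnma1 (-0.16) and Kcnq3 (-0.18), and the sodium channel gene Scn2a (-0.17). The list lost its call without control replicate 1 and without cKO replicate 3 (camera adjusted p up to 0.558), and also with both libraries that stand apart left out (0.353).

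Excitatory neuron markers had 15 of 17 members negative, with a median of -0.07 (camera adjusted p 0.0193). With an estimated correlation the adjusted p was 0.795. The synaptic vesicle gene Sv2b stood at -0.14 (SE 0.059) and the transcription factor gene Rorb at -0.19 (SE 0.099). This list too lost its call without control replicate 1 and without cKO replicate 3 (camera adjusted p up to 0.386), and with both libraries that stand apart left out (0.745).

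Mouse orthologs of risk genes for schizophrenia and bipolar disorder had 10 of 12 members negative, with a median of -0.07 (camera adjusted p 0.0230). An estimated correlation gave an adjusted p of 0.795. Ank3, encoding the ankyrin of the axon initial segment, stood at -0.14 (SE 0.067), and the glutamate receptor genes Gria3 and Grin2a at -0.11 and -0.15. The call was lost in 4 of the 8 fits that leave out 1 library, those without control replicate 1 or 2 and without cKO replicate 2 or 3 (camera adjusted p up to 0.306), and with both libraries that stand apart left out (0.0657).

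The remaining synaptic lists did not pass over all 8 libraries with group as the only term and without GC-content offsets. Presynaptic release genes (44 tested, median -0.03) had a camera adjusted p of 0.117, with the synapsin gene Syn3 at -0.32 (SE 0.10) and the active zone gene Erc2 at -0.17 (SE 0.064). Excitatory postsynaptic receptors and scaffolds (45 tested, median -0.03) had a camera adjusted p of 0.205, with the neuroligin gene Nlgn1 at -0.19 (SE 0.069). With GC-content offsets both lists passed towards lower values (camera adjusted p 0.0171 and 0.00666), but not with an estimated correlation (0.786 for each). GABA receptor and inhibitory synapse genes (23 tested, median -0.05) had a camera adjusted p of 0.0626, with Gabrb2 at -0.16 (SE 0.067). Inhibitory neuron markers (18 tested, median -0.05) had a camera adjusted p of 0.677, with Npy at 0.17 and Sst, encoding somatostatin, at 0.11.

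Cholesterol biosynthesis genes had 18 of 25 members negative, with a median of -0.05 (camera adjusted p 0.0183). The list did not pass with an estimated correlation (adjusted p 0.795). Fdps, a farnesyl diphosphate synthase, stood at -0.18 (SE 0.062), not past edgeR's threshold over all genes (adjusted p 0.889) or adjusted over the list alone (0.101). The list lost its call without control replicate 4 and without cKO replicate 4 (camera adjusted p up to 0.138).

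Proteasome subunit genes had 22 of 31 members negative, with a median of -0.04 (camera adjusted p 0.0424). With an estimated correlation the adjusted p was 0.795. The cKO list means all lay below the control ones, by -0.04 on average (exact permutation p 0.0286, adjusted 0.971 over the 46 lists). An exact p of 0.0286 is the smallest possible here, and no list could pass after adjustment unless many reached it together. Among 46 lists, chance alone can bring a list to it. Psmb7 stood at -0.13 (SE 0.069) and Psma2 at -0.11 (SE 0.059). The camera call was lost without control replicate 2 and without cKO replicate 3 or 4 (adjusted p up to 0.178).

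Cytosolic ribosomal protein genes (76 tested, median -0.02) did not pass, with a camera adjusted p of 0.0626, nor did nuclear-encoded respiratory chain genes (75 tested, median 0.03), at 0.490. With GC-content offsets the ribosomal list passed towards lower values (0.00666), but not with an estimated correlation (adjusted p 0.786). The 12 mitochondrially encoded transcripts had a median of -0.0034 and a camera adjusted p of 0.873 over all libraries, or 0.982 with an estimated correlation. Their list mean was -0.43 in cKO replicate 1 and from 0.05 to 0.09 in the other cKO libraries. Without cKO replicate 1 they lay towards higher values in cKO brain, with a camera adjusted p of 0.00141 at the preset correlation. With an estimated correlation in that fit they did not pass (adjusted p 0.847).

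Among cell types, astrocyte markers held the called gene Aqp4. Of 18 tested, 11 had positive log2 fold changes, with a median of 0.05 (camera adjusted p 0.0739). With GC-content offsets the list passed towards higher values (0.0473), but not with an estimated correlation (adjusted p 0.786). Adjusted over the list alone, edgeR called 2 members, Aqp4 and Ntsr2, a neurotensin receptor gene of astrocytes (0.24, SE 0.065, adjusted p 0.0123 over the list and 0.889 over all genes). Slc7a10, an amino acid transporter gene, stood at 0.28 (SE 0.11), and Slc1a2, the main astrocytic glutamate transporter gene, at -0.20 (SE 0.075).

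Endothelial markers had 13 of 17 members negative, with a median of -0.07 (camera adjusted p 0.0183). An estimated correlation gave an adjusted p of 0.795. The drug efflux gene Abcb1a stood at -0.21 (SE 0.074), the VEGF receptor gene Flt1 at -0.17 (SE 0.071) and the junction gene Esam at 0.21 (SE 0.098). The call was lost without control replicate 4 and without cKO replicate 4 (camera adjusted p up to 0.221); the list mean of cKO replicate 4 was -0.15, against -0.05 to -0.03 in the other cKO libraries.

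Choroid plexus markers had 14 of 16 members negative, with a median of -0.17 (camera adjusted p 0.0211). The list did not pass with an estimated correlation (adjusted p 0.837). The water channel gene Aqp1 stood at -0.35 (SE 0.19) and Clic6 at -0.28 (SE 0.15). List means varied between libraries of 1 group, with an SD of 0.28 in control and 0.26 in cKO (exact permutation p 0.486, n = 4). The call was lost without control replicate 1 or 3 and without cKO replicate 3 (camera adjusted p up to 0.724), and with both libraries that stand apart left out (0.703).

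Microglia, oligodendrocyte and mural cell lists did not pass over all 8 libraries with group as the only term. Microglia markers (19 tested) had a camera adjusted p of 0.985 and a median of 0.01, with a mean of -0.02; P2ry12, a purinergic receptor gene of resting microglia, stood at -0.26 (SE 0.080). Oligodendrocyte and myelin markers (20 tested, median 0.06) had a camera adjusted p of 0.205, with Trf at 0.16 and Myrf at 0.18. Oligodendrocyte precursor markers (15 tested, median -0.08) also had 0.205, with Bcas1 at -0.17. Pericyte and smooth muscle markers (13 tested, median -0.04) had 0.642, and meningeal fibroblast markers (16 tested, median 0.02) had 0.899, with Igf2 at 0.67 (SE 0.23).

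Region markers were compared because dissection can differ between brains. Thalamic and habenular genes had 14 of 20 members negative, with a median of -0.08 (camera adjusted p 0.0230). With an estimated correlation the adjusted p was 0.795. Rora, encoding a nuclear receptor, stood at -0.24 (SE 0.071) and was called by edgeR adjusted over the list alone (adjusted p 0.0495), not over all genes (0.889). Slitrk6 stood at -0.39 (SE 0.15) and Adra2b at 0.49 (SE 0.24). The call was lost without control replicate 1 or 3 and without cKO replicate 3 or 4 (camera adjusted p up to 0.185).

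The other region lists did not pass camera over all 8 libraries without GC-content offsets, with adjusted p of 0.380 for cortical projection neuron genes (median -0.03), 0.595 for hippocampal genes (median -0.01), 0.295 for striatal medium spiny neuron genes (median -0.04) and 0.205 for cerebellar genes (median -0.09). They were 0.595 for hypothalamic genes (median 0.03), 0.595 for olfactory bulb genes (median -0.03) and 0.117 for midbrain and hindbrain genes (median 0.10). With the offsets the striatal list passed towards lower values (camera adjusted p 0.0497), but not with an estimated correlation (adjusted p 0.786).

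Genes near Akap11 on chromosome 14 were examined because a targeted locus can carry altered neighbours. Within 5 Mb on either side, 41 genes other than Akap11 were tested and edgeR called 0, against 3 of 16422 elsewhere (two-sided Fisher exact p 1). With so few calls, 0 near Akap11 would be found in nearly any case, so this count cannot show whether neighbours are altered. The 3 include Mmp14, on the same chromosome but outside this window. An unadjusted p under 0.05 was reached by 0 of the 41, against 788 of the 16422 elsewhere (two-sided Fisher exact p 0.265). DESeq2 and limma voom also called 0. The neighbour with the lowest p-value was Wbp4 (unadjusted p 0.0561). Gene order came from an older build than the counts.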

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

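The test of depth and the bounds of the GC-content test were set before their results were seen. The resampling of genes in the GC-content test was chosen only after. The correlations of single libraries with GC content were already known when the bounds of that test were set. Each value here is a library set apart from the other 3 of its group by a gap large against the group's range. This was so for 6 of 78 groups of 4 values examined, where chance gives about 5%.

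Of the 6 values, 4 belong to cKO replicate 1. It held Prkar1a at 706 CPM, against 793 to 810 CPM in the other cKO libraries. It held Gsk3b, a kinase gene of the AKAP11 complex, at 206 CPM, against 263 to 267 CPM. Mitochondrially encoded genes took 2.77% of its reads in genes, against 3.42% to 3.48%, and their list mean was -0.43 on the log2 scale, against 0.05 to 0.09. The endothelial list mean set 2 further libraries apart: control replicate 2 at -0.057, with the other controls from 0.01 to 0.02, and cKO replicate 4 at -0.153, with the others from -0.05 to -0.03.

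The pattern weighed is that cKO replicate 1, the library with the fewest reads in genes, stood apart on the first principal component. After all libraries were thinned to its reads in tested genes, 97.2% of its distance from the others was left, which argues against that lower number of reads. For GC content, the values of cKO replicate 1 correlated with it across genes more strongly than in any other library (Spearman's rho 0.66, next -0.43). Genes are not independent replicates. Per-library GC offsets left 91.7% of the distance, with a spread of 80.1% to 93.4% over 50 resamplings of genes. Had GC content been the cause, the offsets were predicted to bring the distance under 50%. The values lie above that, which argues against GC content as the source of most of the distance. A smaller part stays open, as the 90% bound against any GC-content cause was passed by less than the spread. Without that spread, added once the value was known, the bound alone would have counted against GC content. The higher shares of ambiguous, low-quality and unaligned reads in cKO replicate 1 were not tested as a cause. No biological explanation was tested, and the other 3 cKO libraries did not share the position.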

How the results depend on the processing

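The GC-content offsets, the fit without control replicate 1 and cKO replicate 1, and an estimated correlation in fits with offsets, covariates or libraries left out were chosen only after the data were seen; all other alternatives here were planned. Akap11, Aqp4, Mmp14 and Nxph1 kept their direction in all 20 alternatives and passed in 17, 15, 9 and 8 of them. Over these, edgeR, DESeq2 or limma adjusted p for Akap11 ran from 1.91e-11 to 0.104. With 1 surrogate variable, Akap11 was at -0.47 (edgeR adjusted p 0.0676) and 1 gene was called, 1 higher and 0 lower. With each library left out in turn, Akap11 ranged from -0.55 to -0.42, genes called from 0 to 3, higher genes from 0 to 1, lower genes from 0 to 2 and lists past camera from 3 to 15. The 0 genes came without control replicate 2 and without cKO replicate 2, where 720 and 817 genes had an unadjusted edgeR p under 0.05; 3 lists passed without cKO replicate 3, 14 without cKO replicate 1 and 15 without control replicate 3. Genes called were 7 (5 higher) with no low-count filter, over 32202 genes, where Igsf1, Gfap and Gm21887 were added; Gm21887 was named after its values were seen. Library totals gave 3 genes, 1 of them lower; limma voom gave 2 (1 higher, 1 lower), as did the fit without both libraries that stand apart. The replicate block also gave 2 (1 higher, 1 lower), with Mmp14 and Nxph1 at edgeR adjusted p of 0.0906 and 0.221; 2 lists were gained, cytosolic ribosomal proteins and blood cell markers. Nothing in the labels says that equal replicate numbers pair libraries, and no clear pairing was seen. Own-number correlations were 0.0052, 0.025, 0.043 and 0.049, and the highest with another number was 0.105. Of 4 control libraries, 2 correlated best with their own number, so that with so few libraries pairing is not excluded. DESeq2, its size factors, a mean CPM of at least 1, sample weights, GC-content offsets and removal of mitochondrially encoded genes each called the same 4 genes. Lists past the threshold were 0 with an estimated correlation and 0 with fry; with GC-content offsets they were 14, and 0 with an estimated correlation in that fit or in any of the 11 with libraries left out, the block or the surrogate variable. Mitochondrially encoded transcripts turned from lower, not past the threshold, to higher and past it without cKO replicate 1 (camera adjusted p 0.00141), with 1 surrogate variable (0.000316) and without both libraries that stand apart (0.00253); leaving out each library gave 0.00141 to 0.813. With an estimated correlation the list did not pass in these 3 fits (adjusted p 0.847, 0.843 and 0.919). Counting Akap11 among the genes within 5 Mb gives 1 called by construction; 2 Mb and 10 Mb gave 0. Of 3731 alternative values of single genes and 831 of lists, 27 and 76 changed sign with neither value past the threshold. Most of these genes had been picked for low p-values in the same libraries, which favours kept signs. The causes of these shifts were not tested, except that fewer libraries enter when 1 is left out. At this depth and number of libraries, in simulation 37.6% of genes with a log2 change of 0.32 and 69.6% of those changed 1.5-fold were recovered. A sex covariate was not run, as all libraries read as male.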

Other observations

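The tests of GC content, of single libraries and of astrocyte share for Aqp4, Mmp14 and Nxph1, and the test of immediate early genes, were chosen only after the results were seen; the splits and the test of genes between Mmp14 and Akap11 were set before theirs were seen.

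Glial and stress states not described so far gave no list past camera over all 8 libraries with group as the only term. Among 15 reactive astrocyte genes, Gfap, the intermediate filament gene of astrocytes, stood at 0.33 (SE 0.11) and Steap4 at 0.73 (SE 0.38), while Cd44 stood at -0.29 (SE 0.15); the camera adjusted p was 0.899 and the list's median of -0.08 differed in sign from its mean of 0.01. Disease-associated microglia genes had an adjusted p of 0.956 (17 tested, median 0.0022), with Csf1 at 0.17, and interferon-stimulated genes 0.205 (25 tested, median -0.09). The unfolded protein and integrated stress response had 0.956 (29 tested, median -0.01, mean 0.01), with Atf5 at 0.21, and cytosolic heat shock proteins 0.595 (19 tested, median -0.03, mean 0.00062), with Cryab at 0.18. Neurogenesis and proliferation genes had 0.899 (19 tested, median -0.01), ependymal markers 0.595 (12 tested, median -0.03) and blood cell markers 0.205 (5 tested, median -0.07, with the haemoglobin gene Hbb-bs at -0.79, SE 0.64).

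The neuropeptide list held Nxph1, its only member called over all genes or adjusted over the list alone (edgeR adjusted p 0.000262 over the list). Its 33 tested members had a median of -0.0011 and a mean of 0.01 (camera adjusted p 0.205). Nucb2, the precursor gene of nesfatin, stood at -0.28 (SE 0.10), Penk at -0.12 (SE 0.061) and Npy at 0.17 (SE 0.095).

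The first pattern is that Aqp4, Mmp14 and Nxph1 passed besides Akap11. A GC-content trend is argued against, since each of the 3 genes kept at least 92.6% of its log2 fold change with GC-content offsets; a larger share of astrocytes as the source of Aqp4 is argued against by the median of 0.051 over the 17 other astrocyte markers (SD 0.11, highest Slc7a10 at 0.28), far under 0.46. No single library carried these folds, as each gene kept at least 89.9% of its log2 fold change whichever library was left out. The genes had been picked as passing the test, which favours such folds, so no conclusion on a cause is drawn from this. Flanking alleles of another strain at Mmp14, on the chromosome of Akap11, cannot be told apart from other causes: 3.81% of 210 genes between the 2 had an unadjusted p under 0.05 (exact 95% interval 1.66% to 7.37%), against 4.84% on other chromosomes. Chance is not excluded either, as 2 of the 35 splits of the 8 libraries into 4 and 4, the real one included, called at least as many genes (4 in the real split, 9 in the highest other), so an effect of Akap11 loss on these genes stays an open hypothesis.

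The split with 9 genes set control replicates 1, 3 and 4 and cKO replicate 3 against the rest. Of its genes 5 were immediate early genes, Arc, Dusp1, Fos, Nr4a1 and Egr1, named after the split was seen. Of the 34 other splits, 31 called 0 genes by edgeR and 2 called 1.

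The second pattern is the shift of immediate early genes towards higher values in cKO brain. Differences between libraries within the groups may account for it: the exact permutation p of the list mean per library was 0.286, and the groups overlapped. For the 9 lists past camera as a whole, chance is not excluded, since 23 of the 35 splits gave at least as many lists (9 in the real split, 21 in the highest other). Handling or activity of the mice before the brains were taken is not given in the sources used here and was not tested, and neither was an effect of genotype on activity.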
